A study of Rattus norvegicus with 8 samples.

How the data were processed

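Skeletal muscle of the thigh from 8 Wistar Han rats was measured on Illumina rat expression bead arrays, 1 array per rat. Per the labels, 4 rats received standard chow and 4 received chow with 150 ppm of a sulfonyl isoxazoline, compound 177, for 28 days. The muscle was ground under liquid nitrogen, and RNA was extracted with a column kit, treated with DNase and converted to biotin-labelled cRNA, per the labels' protocols. The design text gives 4 rats per group, so the replicates were taken as separate animals.

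The deposited non-normalized table holds a linear intensity per probe and array for 22523 probes, without normalization between arrays, per the file headers. Beside each intensity the authors deposited a detection p-value, which moves in steps of 1 in 825. The authors' deposited normalized table holds linear intensity values that were not used for the main results. Its sorted values are identical within 2 sets of 4 arrays, as a quantile normalization leaves them: replicates 1 and 2 of both groups form set 1, and replicates 3 and 4 of both groups form set 2. The series' value table is identical to it, with a largest difference of 0; it is on a linear scale, is not centred and is not a ratio. Scanner software, background step and the arrays that entered each set are not given in the sources used here. The 8 detection p columns of the normalized table were not used.

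Intensities were corrected and quantile-normalized together with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16, and taken to log2. A probe was kept if its detection p was below 0.05 on at least 4 of the 8 arrays, which left 10212 probes. Gene symbols came from the platform's probe annotation: 13793 probes had 1 symbol, 0 had several and 8730 had none and are unnamed here. Of these probes, 13752 matched a gene of the rat reference annotation (GRCr8) by gene identifier, and 0 symbols differed from the current one. Among the tested probes 7441 were named, for 7299 genes, and 2771 were unnamed. Of the tested genes, 133 had several probes, and gene lists took the probe with the highest mean signal.

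Groups were compared with lmFit and eBayes of limma, without covariates, with Benjamini-Hochberg adjustment over the tested probes. Gene lists were tested with camera (inter-gene correlation preset to 0.01), for 47 lists of which 45 had at least 5 measured genes; lymphocyte markers and skin and epithelial markers had fewer. The lists comprised 37 pathways and 10 sets of cell type markers. Mean deviations per array were also compared between groups with a two-sided exact permutation test, whose smallest possible p is 0.029. Test, lists, a naming rule and most alternatives were set before the data were examined. Named genes are the 8 with the smallest p in each direction, a fixed set of 22 genes of mitochondrial stress, fuel use, atrophy and fibre type where measured (1 of them is not reported here), and 2 members with the smallest p of each called list. The rule asked for the largest changes past the threshold, with this fallback when fewer than 20 probes passed. It allowed more members of each called list than the 2 named here, so that part departs from the rule.

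On simulated data with the spread of these arrays and 10212 probes, the test recovered 8.96% of changes of 0.5, 83.6% of changes of 1 and 97.0% of changes of 2 on the log2 scale, with 3 false calls among 129. The changes were planted together, in 67, 67 and 66 probes, which loosens the adjusted threshold. With few true changes, recovery at these sizes would be lower. The simulation drew probes independently and held no batch or shared composition. A list shifted by 0.25 was called, and 0 lists without a shift were. Precision is limited by the number of arrays: the median standard error of a fold change was 0.16, and the median half-width of its 95% confidence interval was 0.35, a 1.27-fold change.

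Whether the replicate numbers pair the rats was checked from the data, since the labels do not say so. Deviations from the group mean correlated between control and compound 177 arrays of number 1, 2, 3 and 4 at 0.24, 0.47, 0.12 and 0.43, and 6 of the 8 arrays correlated best with their own number. Arrays of unlike number averaged 0.13 within a normalization set and -0.21 between sets. Numbers 2 and 4 lie well above that 0.13 but number 3 does not, so the numbers may pair the arrays without this being settled. The control and compound 177 arrays numbered 2 also had the lowest array weights (0.572 and 0.541, others 0.958 or more). They had the lowest maximum intensities (42838 and 43195) and the fewest detected probes (9634 and 9261) as well. Their correlation of 0.47 therefore need not come from pairing. The main fit and its standard errors leave the numbers aside, and a fit with the number as a block was an alternative.

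Alternatives were another background correction, median scaling, no background correction, the authors' normalized table, other filters, array weights, a trended robust prior, each array left out, averaged probes, an estimated correlation and the rotation test fry. Fits with the normalization set as a block, within each set, without both arrays numbered 2, and the exact permutation of list means were chosen after seeing the data.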

Results

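Transcript levels in thigh skeletal muscle were compared between 4 control rats and 4 rats fed compound 177, a sulfonyl isoxazoline, at 150 ppm in the diet for 28 days. The series title gives the purpose as modelling the mitochondrial toxicity of such compounds in muscle. Median intensity per array ran from 97.5 to 124.7, and between 9261 probes (compound 177 replicate 2) and 10620 probes (control replicate 3) had a detection p below 0.05. Arrays correlated pairwise at 0.965 to 0.991. Levels and differences are on the log2 scale, and differences are compound 177 minus control with n = 4 rats per group.

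In rats fed compound 177, genes of respiratory complex I, cytochrome c oxidase, ATP synthase, the mitochondrial ribosome and branched-chain amino acid breakdown were slightly higher as groups, with median differences of 0.15 to 0.16. Genes of the extracellular matrix and of slow muscle fibres were lower as groups, with median differences of -0.53 and -0.66. The slow-fibre list mean differed by -0.08 within normalization set 1 and by -1.40 within set 2. These group calls were made with a preset correlation between genes, and 0 of the called lists held when the correlation was estimated. For proteasome subunits, adipocyte markers and calcium handling the estimate (-0.0011, -0.018 and -0.0049) lay below the preset 0.01. For these lists a higher correlation therefore does not account for the loss of the call. No single gene passed the test: with limma, 0 probes were higher and 0 lower at an adjusted p below 0.05, and the smallest adjusted p was 0.9999. Among the 10212 probes, 396 had an unadjusted p below 0.05 (231 higher, 165 lower), against 511 expected by chance. This comparison depended on the fit: 657 had such a p with the replicate number as a block, 560 with the normalization set as a block, and 126 with median scaling. A count below that expected by chance is therefore no evidence that nothing changed.

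The 8 genes with the smallest p among the higher ones did not pass, all at an adjusted p of 0.9999, and nor did the 8 lower ones. The largest of these differences was that of Eef2k, the kinase that inhibits elongation factor 2 and so slows protein synthesis, at 10.41 ± 0.43 (SD, n = 4) in treated and 9.28 ± 0.36 in control muscle, a difference of 1.14 (SE 0.24). Within normalization sets 1 and 2 this difference was 1.59 and 0.69. Fads6, a fatty acid desaturase family member, was higher by 0.76 (SE 0.18), and Slc1a1, a glutamate transporter, by 0.67 (SE 0.17). Inpp4b, a phosphoinositide phosphatase, was higher by 0.52, Lysmd2 by 0.49, Lamtor4, a subunit of the lysosomal Ragulator complex, by 0.47, Prkg2, a cGMP-dependent kinase, by 0.47, and Cep20 by 0.44. Lower values were found for Tpm3, the slow-fibre tropomyosin, at -0.66 (SE 0.20), Cysltr1, a leukotriene receptor, at -0.57 (SE 0.15), and Bcl6, a transcriptional repressor, at -0.55 (SE 0.16). Nr3c1, the glucocorticoid receptor, differed by -0.51 (SE 0.15), Zfp36l2, an mRNA decay factor, by -0.48, Setd5 by -0.47 and Ncor1, a nuclear receptor corepressor, by -0.45 (SE 0.12). Usp20, a deubiquitinase, was not well above background on any treated array, so its size is uncertain. With treated values raised to the lowest signal above background on each array (5.32 to 5.55), its mean was 1.10-fold lower there. That value makes no allowance for sampling error, and the control mean of 5.56 was itself near background. Usp20 passed the filter only through the 4 control arrays and was not tested in runs that left out a control. The sizes depended on the background correction: for 9 of these 16 genes the difference as reported was over 1.5 times the smallest of those under another correction, under no correction or in the authors' normalized table, with the sign kept in all 16. Under these settings Fads6 differed by 0.393 to 0.474, Slc1a1 by 0.387 to 0.453, Inpp4b by 0.229 to 0.295 and Prkg2 by 0.209 to 0.262. Cysltr1 differed by -0.252 to -0.324 and Nr3c1 by -0.225 to -0.291, and Eef2k by 1.03 to 1.06. In all, the 4 values of each group did not overlap for 246 probes, 2.41% of those tested, where chance gives 2.86%. That chance value takes all arrays as exchangeable and leaves the normalization sets and replicate numbers aside.

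**Figure D1:**
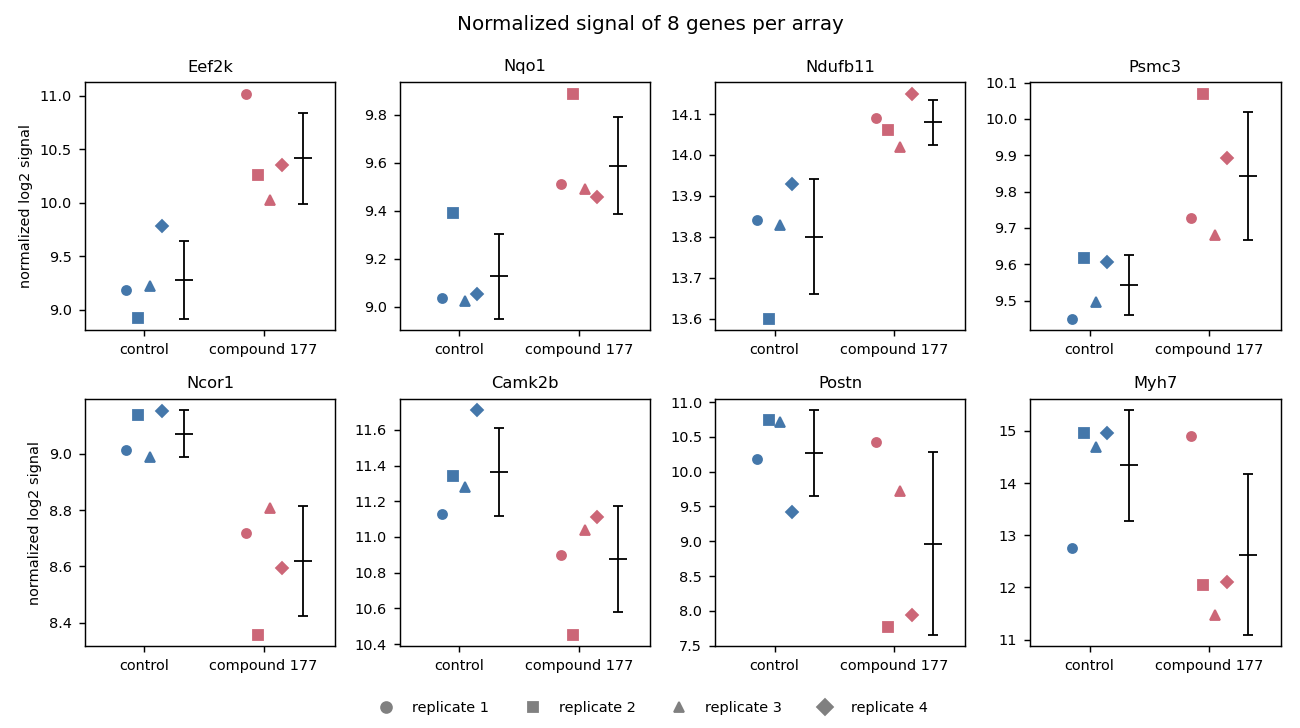
Normalized log2 signal (vertical axes, each panel with its own range) of 8 genes in control and compound 177 muscle; each symbol is 1 array, with the replicate number by shape, and the bar to the right of each group is the mean ± SD (n = 4). Eef2k, Nqo1, Ndufb11 and Psmc3 are higher and Ncor1 and Camk2b lower in every treated array than in any control array, while Myh7 is near 12.8 in control replicate 1 and near 14.9 in compound 177 replicate 1.

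Of the 45 lists tested, 9 were called higher and 10 lower by camera. Within these lists 0 members passed over all probes and 0 passed when adjusted over the list alone. Some called lists share members, so their calls are not independent. Hibch is in the branched-chain and fatty acid lists. Cdkn1a is in the regeneration and glucocorticoid lists, and Fbxo32 in the atrophy and glucocorticoid lists. For respiratory complex I, which feeds electrons from NADH into the chain, 24 of 26 measured members were above control, with a median of 0.16 (adjusted p = 2.63e-05, and adjusted p = 0.358 with an estimated correlation). Ndufb9 was higher by 0.29 (SE 0.11) and Ndufb11 by 0.28 (SE 0.11). In the mitochondrial ribosome list 42 of 46 members were higher, with a median of 0.15 (adjusted p = 6.97e-06, and adjusted p = 0.358 with an estimated correlation). Mrpl19 was higher there by 0.28 (SE 0.13), whereas Mrpl18 differed by -1.88 (SE 0.80), with -0.38 in set 1 and -3.39 in set 2. Cytochrome c oxidase genes had a median of 0.15 with 12 of 13 members higher, among them Cox7b (0.21, SE 0.11) and Cox5b (0.18, SE 0.11), and ATP synthase genes a median of 0.16 with 10 of 12 higher, among them Atp5mg (0.24, SE 0.14) and Atp5mc1 (0.21, SE 0.11). With an estimated correlation both lists had an adjusted p = 0.358. Within set 1 and set 2 the list mean differed by 0.19 and 0.08 for complex I, and by 0.19 and 0.05 for the mitochondrial ribosome. With 1 array left out at a time, complex I and the mitochondrial ribosome were called in 8 of 8 runs, but neither was called within set 2 alone. Cytochrome c oxidase was not called without control replicate 1 or compound 177 replicate 2 (adjusted p up to 0.0624), and ATP synthase not without control replicate 3 or compound 177 replicate 1 or 4 (up to 0.0772). Within set 2 alone cytochrome c oxidase was not called, and ATP synthase was called in neither set.

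Lists of mitochondrial fuel use were called in the same direction. Branched-chain amino acid catabolism was higher in 13 of 15 members, with a median of 0.15 (adjusted p = 0.289 with an estimated correlation), including Dbt, a core subunit of the branched-chain dehydrogenase complex (0.34, SE 0.13; 0.573 in set 1 and 0.10 in set 2), and Hibch of the valine branch (0.26, SE 0.10). In the list of the TCA cycle and pyruvate dehydrogenase 19 of 22 members were higher (median 0.15, adjusted p = 0.563 with an estimated correlation). They included the mitochondrial pyruvate carrier Mpc2 (0.40, SE 0.17) and Mdh1 (0.25, SE 0.11), the cytosolic malate dehydrogenase rather than the mitochondrial one. Fatty acid uptake and oxidation was higher in 22 of 30 members (median 0.14, adjusted p = 0.563 with an estimated correlation), with the carnitine carrier Slc25a20 at 0.39 (SE 0.17). Proteasome subunits were higher in 24 of 33 members (median 0.08, adjusted p = 0.289 with an estimated correlation), among them Psmc3 (0.30, SE 0.12) and Psme2 (0.28, SE 0.16). It was the one list for which the per-array means of the groups were fully separated (exact permutation p = 0.029, the smallest that n = 4 per group can give, and 0.429 after adjustment over the 45 lists). Interferon response genes were higher in 16 of 20 members (median 0.17, adjusted p = 0.358 with an estimated correlation), but the members with the smallest p went opposite ways: Psmb9, an immunoproteasome subunit, differed by 0.60 (SE 0.19) and Ifit1 by -0.83 (SE 0.35). Ifit1 was above background on 1 of 4 treated arrays, so this size is uncertain. It was -0.42 with values raised to the lowest signal above background on each array, and -0.444 without background correction. With the replicate number as a block, Ifit1 passed when adjusted over the list alone (adjusted p = 0.00747), a call that rests on these treated values near background, as did Plvap (-0.59), an endothelial gene outside the naming rule and named after its value was seen (adjusted p = 0.0104). Of these lists, branched-chain amino acid catabolism was called in 8 of 8 runs with 1 array left out. Within set 2 alone the lists of branched-chain amino acid catabolism, the TCA cycle and fatty acid oxidation were not called, and within set 1 alone the proteasome and interferon lists were not. The TCA cycle list was not called without control replicate 1 or compound 177 replicate 4 (adjusted p up to 0.153), nor was the interferon list (up to 0.0911). Fatty acid oxidation was not called without control replicate 1 or 3 or compound 177 replicate 4 (up to 0.301), and proteasome subunits not without control replicate 3 or 4 or compound 177 replicate 2 (up to 0.113).

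**Figure D2:**
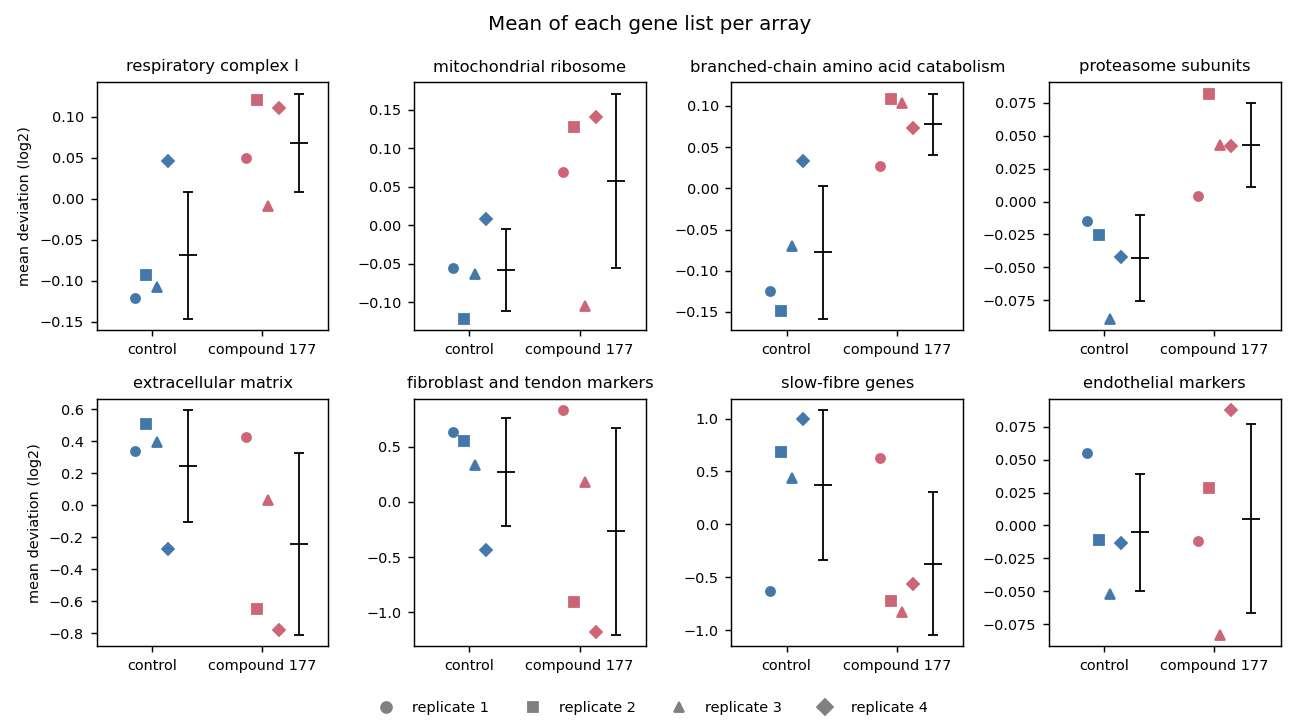
Mean deviation of 8 gene lists from each gene's mean over all arrays (log2; each panel has its own range), per array, for control and compound 177 muscle; symbols give the replicate number and the bar to the right of each group is the mean ± SD (n = 4). The slow-fibre list lies at -0.63 in control replicate 1 and 0.63 in compound 177 replicate 1, against the direction of the other arrays of each group, and the proteasome list is higher in every treated array.

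Connective tissue genes were lower. In the extracellular matrix list 30 of 31 members had lower values, with a median of -0.53 (adjusted p = 3.47e-09, and adjusted p = 0.374 with an estimated correlation). Postn, the matrix protein periostin, differed by -1.30 (SE 0.59) and Col5a1 by -0.71 (SE 0.28). Markers of fibroblasts and tendon were lower in 15 of 16 members, with a median of -0.49 (adjusted p = 0.503 with an estimated correlation), including Cilp (-1.17, SE 0.53) and Col3a1 (-0.60, SE 0.32). The spread between rats was wide: the matrix list mean was 0.24 ± 0.35 in control and -0.24 ± 0.57 in treated muscle (SD, n = 4; exact permutation p = 0.23). Its difference was -0.54 within set 1 and -0.43 within set 2. Endothelial markers did not move with it, at a median of 0.05. Macrophage markers were lower in 13 of 15 members (median -0.29, adjusted p = 0.563 with an estimated correlation), with the complement subunit C1qb at -0.79 (SE 0.36) and Gpnmb at 0.24 (SE 0.13). Nerve and Schwann cell markers were lower in 8 of 9 members (median -0.28, adjusted p = 0.289 with an estimated correlation), with the neurotrophin receptor Ngfr at -0.28 (SE 0.10) and the sodium channel Scn7a at -0.36 (SE 0.17). Adipocyte markers were lower in 11 of 15 members (median -0.16, adjusted p = 0.289 with an estimated correlation), although Fabp4, the adipocyte fatty acid binding protein, differed by 0.25 (SE 0.10) and Car3, which muscle also expresses, by -0.46 (SE 0.21). Car3 differed by -0.09 in set 1 and -0.83 in set 2, the pattern of the slow-fibre genes below, so it may not reflect adipocytes. The matrix and nerve lists were called in 8 of 8 runs with 1 array left out (the nerve list not within set 1 alone), and the fibroblast list in 7, not without compound 177 replicate 4 (adjusted p = 0.0501). Macrophage markers were not called without control replicate 2 or compound 177 replicate 2 or 4 (adjusted p up to 0.267), and adipocyte markers not without control replicate 2 or 3 or compound 177 replicate 2, 3 or 4 (up to 0.133). Within set 2 alone macrophage markers were not called. Adipocyte markers were called in neither set, nor with either other filter on dim probes.

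Slow-fibre genes were lower in 12 of 15 members, with a median of -0.66 (adjusted p = 8.79e-05, and adjusted p = 0.503 with an estimated correlation). Myh7, the slow myosin heavy chain, differed by -1.71 (SE 0.75, 95% confidence interval -3.40 to -0.02). The list's difference lay in set 2: its mean differed by -0.08 in set 1 and by -1.40 in set 2, and that of Myh7 by -0.38 and -3.04. The set 1 values hold control replicate 1, where Myh7 was 12.76 against 14.69 to 14.95 in the other controls, and compound 177 replicate 1, where it was 14.91 against 11.47 to 12.10 in the other treated rats. Over all 8 arrays the list mean gave an exact permutation p = 0.20, and the list was not called in set 1 alone. Adjusted over the list alone, 8 members passed without control replicate 1 and 7 without compound 177 replicate 1, among them Myh7 (-2.23 and -2.47). Markers of fast fibres were not called (median -0.02), and Myh4, the fast myosin heavy chain, differed by -0.29 (SE 0.26).

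Calcium handling genes were lower in 15 of 21 members (median -0.07, adjusted p = 0.289 with an estimated correlation), with Camk2b, a calmodulin kinase subunit, at -0.49 (SE 0.18) and Atp2a2, the slow-fibre calcium pump, at -1.13 (SE 0.51; -0.246 in set 1 and -2.01 in set 2). This list shared 2 members with the slow-fibre list. Muscle regeneration and embryonic genes were lower in 15 of 21 members (median -0.32, adjusted p = 0.289 with an estimated correlation), including embryonic myosin Myh3 (-1.87, SE 0.67; -0.942 in set 1 and -2.81 in set 2) and troponin Tnnt2 (-1.68, SE 0.74; -2.83 and -0.527). Muscle atrophy genes were lower in 13 of 17 members (median -0.19, adjusted p = 0.374 with an estimated correlation), including Myog (-0.35, SE 0.16) and the lysosomal protease Ctsl (-0.27, SE 0.16), but the list mean differed by -0.38 in set 1 and by 0.08 in set 2. Glucocorticoid-responsive genes were lower in 16 of 21 members (median -0.11, adjusted p = 0.358 with an estimated correlation), with Cdkn1a, a cell cycle inhibitor, at -1.27 (SE 0.67) and Angptl4, a lipoprotein lipase inhibitor, at -0.62 (SE 0.36). Without control replicate 2 these were -0.744 and -0.33, and in set 2 Cdkn1a differed by 0.29. Cdkn1a was above background on 3 arrays of each group and near background in set 2, so its sizes are uncertain. The regeneration list was called in 8 of 8 runs with 1 array left out, but not within set 2 alone. Muscle atrophy was not called without control replicate 2 or compound 177 replicate 1 or 2 (adjusted p up to 0.182). Calcium handling was called in 2 of 8 runs, without control replicate 1 or 4 (adjusted p up to 0.11 in the others), and the glucocorticoid list in 3 of 8, without control replicate 1 or 4 or compound 177 replicate 4 (up to 0.213). With median scaling neither of these lists was called. Calcium handling was called in neither set, and the atrophy and glucocorticoid lists were not called within set 2 alone.

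**Figure D3:**
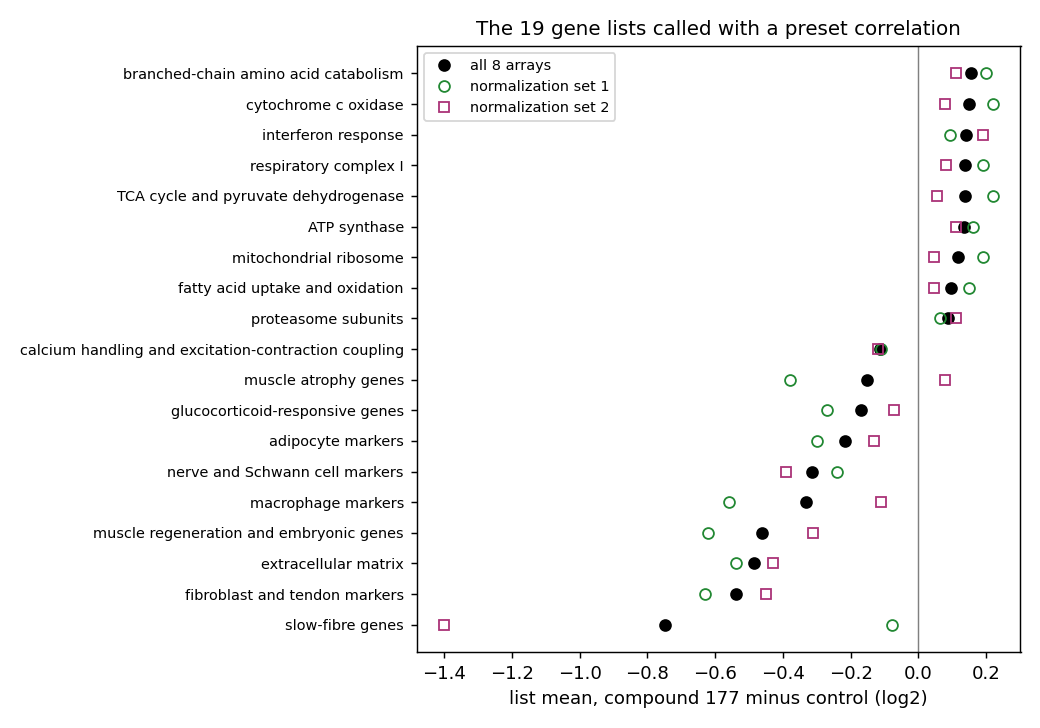
Difference of the list mean between compound 177 and control (horizontal axis, log2) for the 19 called lists, over all 8 arrays (filled circles) and within normalization set 1 (open circles) and set 2 (open squares), each set with 2 arrays per group. The slow-fibre list differs by -0.08 in set 1 and -1.40 in set 2, and the muscle atrophy list is the one whose sign differs between the sets.

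The other 26 lists were not called, at adjusted p from 0.14 to 0.99. They included respiratory complexes II and III (7 of 9 members higher, median 0.10, adjusted p = 0.152), mitochondrial biogenesis and dynamics (median 0.04), the integrated stress response (median -0.01), the mitochondrial unfolded protein response (0.02), NRF2 and glutathione defence (0.03), PPAR targets (-0.03), glycolysis (-0.005), hypoxia-inducible genes (-0.03) and xenobiotic metabolism (-0.10). Among cell type markers, those of blood (-0.28), smooth muscle and pericytes (-0.12) and neutrophils and mast cells (-0.06) were not called either, and the blood list was called lower without control replicate 2 (adjusted p = 0.00753). The median, the mean and the test differed in sign for 8 of these lists: circadian clock, hypoxia, immediate early, cytosolic ribosome, proliferation, PPAR, NRF2 and glycolysis. Of the genes chosen in advance, Nqo1, an NRF2 target that reduces quinones, stood apart: it was 9.59 ± 0.20 in treated and 9.13 ± 0.18 in control muscle, a difference of 0.46 (SE 0.14, 95% confidence interval 0.15 to 0.78) without overlap of the groups, yet at an adjusted p of 0.9999. Its difference was 0.49 in set 1 and 0.44 in set 2. Hmox1, another NRF2 target, differed by -0.02 (SE 0.20). The stress transcription factors Atf3 (-0.15, SE 0.48) and Ddit3 (0.18, SE 0.24), the fuel genes Pdk4 (-0.19, SE 0.17), Cpt1b (0.14, SE 0.14), Ucp3 (-0.05, SE 0.32), Hk2 (-0.07, SE 0.27) and Ldha (-0.05, SE 0.12), citrate synthase Cs (0.22, SE 0.20) and the coactivator Ppargc1a (0.23, SE 0.24) each had a 95% confidence interval that included 0. The ubiquitin ligases of muscle wasting, Fbxo32 and Trim63, differed by -0.45 (SE 0.34) and 0.02 (SE 0.17). Probes for Fgf21, Gdf15, Trib3, Asns and Cyp1a1 were not well above background on any array.

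Of the 50 named genes outside the 16 with the smallest p, 11 also had differences over 1.5 times the smallest under another background correction, under no correction or in the authors' normalized table: Dbt (0.166 to 0.202 under these settings), Ngfr (-0.121 to -0.156), Scn7a (-0.161 to -0.204), Cdkn1a (-0.718 to -0.845), Angptl4 (-0.397 to -0.452), Ifit1, Psmb9, Gpnmb, Myh3, Hmox1 and Ppargc1a. With 1 array left out, 21 of the 66 named genes had a difference over 1.5 times smaller than reported or of the other sign. Of these, 8 are named for their p. Without control replicate 2 they were Cdkn1a, Angptl4, Ctsl (-0.134) and Tnnt2 (-0.872). Without compound 177 replicate 2 they were Col3a1 (-0.346), C1qb (-0.466) and Psme2 (0.163), and without compound 177 replicate 4 Atp5mg (0.159). Between the sets, the differences of 12 named genes had opposite signs, and those of 13 others were over 3 times apart: Nr3c1, Car3, Dbt, Atp2a2, Cox5b, Cox7b, Mrpl18, Mrpl19, Ctsl, Myog, Tnnt2, Myh7 and Mdh1. Of the 19 called lists, 7 had a mean difference over 1.5 times smaller with 1 array left out. Without compound 177 replicate 4 these were extracellular matrix (-0.31 in place of -0.485), fibroblast and tendon markers (-0.23 in place of -0.539) and interferon response (0.063 in place of 0.14). Without compound 177 replicate 2 they were macrophage markers (-0.11 in place of -0.333) and muscle atrophy (-0.075 in place of -0.153). Without control replicate 1 they were the TCA cycle (0.083 in place of 0.137) and fatty acid oxidation (0.051 in place of 0.097). The list count depended on single rats too: 11 lists were called without compound 177 replicate 4 and 12 without compound 177 replicate 2. Compound 177 replicate 2 had the lowest array weight of the 8 arrays (0.541). Within sets 1 and 2, which hold 2 arrays per group, 13 and 8 lists were called, and with the set as a block 0 probes and 19 lists.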

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

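The tests of explanations in this part were chosen after the result was seen; the test for a rat that stands apart from the 3 others of its group was set before the data were examined. It was applied to 226 groups of 4 values (named genes, gene lists and array measures) and marked 13, where chance gives about 11. As a number, that is close to chance.

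The slow-fibre program differed among rats of the same diet. Myh7 was 12.76 in control replicate 1, against 14.69 to 14.95 in the 3 other controls. In compound 177 replicate 1, Atp2a2 was 14.24 (others 12.37 to 12.61) and Myh3 8.29 (others 5.66 to 6.06). With the labels as given, control replicate 1 goes against an effect of the compound as the whole cause, since its slow-fibre list mean lay at -1.34 relative to the 3 other controls (their SD 0.28), but with the labels of the 2 arrays numbered 1 exchanged it joins the treated arrays, so such an effect stays open. Pieces of thigh muscle with unequal shares of slow fibres may contribute: the smaller range within a group was 1.46, above the group difference of -0.75 in size, and 13 of 15 members were lowest in control replicate 1 among controls. This rests on the 2 arrays numbered 1: without control replicate 1 the control range was 0.56 and without compound 177 replicate 1 the treated range was 0.27, each below the difference of -1.1 in size, so this stays open too. A range of single values also readily exceeds a difference of group means, so the comparison cannot decide. Exchanged labels of the 2 arrays numbered 1 cannot be told apart from unequal shares of slow fibres. Outside the list, 341 probes had an unadjusted p below 0.05 with the labels exchanged and 394 with the labels as given. Both counts lie below the 511 expected by chance over all tested probes, so they cannot show which labels are right.

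Connective tissue genes were lower in treated muscle as a group but not in each rat. A lower share of all cells other than muscle fibres was tested with the endothelial list. Its range over the 8 arrays was 0.085 times that of the fibroblast and tendon list (0.171 against 2.02). The endothelial list thus showed no such fall, but it cannot speak for other cell types. Its members also varied together less (estimated correlation 0.046 against 0.66), which narrows the range of a list mean. Macrophage, nerve and adipocyte markers were lower too, so a wider fall stays open. Unequal amounts of tendon and fascia in the sampled pieces may contribute: the smaller range within a group was 1.07, against a group difference of -0.54. That range rests on 1 array, since without control replicate 4 it was 0.30 against a difference of -0.77, so this stays open. A range of single values also readily exceeds a difference of group means, so the comparison cannot decide. Among treated rats the tendon gene Tnmd ran from 7.87 to 11.67 and the abundant Col1a1 from 9.48 to 12.84. Of the 16 genes of this list, 15 were above background in all 4 control muscles, and 5 are in the extracellular matrix list too. An effect of the compound on connective tissue cannot be told apart from such sampling with 4 rats per group (exact permutation p = 0.34).

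Mitochondrial genes were slightly higher in treated muscle. Over the 166 measured genes of 8 lists of mitochondrial structure and energy, called or not, the mean difference was 0.11 (SE 0.05), with 0.17 in set 1 and 0.05 in set 2. These genes include the cytosolic Mdh1 of the TCA cycle list. An effect of the compound stays open, as an exact permutation p = 0.11 with 4 rats per group does not decide it. That test leaves the numbered pairs aside. Within pairs 1 to 4 the treated array was higher by 0.13, 0.21, 0.017 and 0.079, and 5 of the 8 lists were higher in all 4 pairs (complex I, cytochrome c oxidase, ATP synthase, TCA cycle, biogenesis and dynamics), but the smallest p that an exact permutation within 4 pairs can give is 0.125. The 5 called lists among these (complex I, cytochrome c oxidase, ATP synthase, TCA cycle, mitochondrial ribosome) gave 0.13 with an exact permutation p = 0.057, a pooling that was chosen from the calls and was replaced for that reason. Less connective tissue signal leaving a larger share to other genes stays open too. It was first tested by the share of signal of 42 connective tissue genes, 0.838% in control and 0.613% in treated muscle, which predicts a rise of 0.00327, but these markers are not all the RNA of such cells, so this sets no bound. In its place, and with the values of both lists already seen, fast-fibre genes were compared: they differed by -0.04, and the mitochondrial lists minus the fast-fibre list by 0.15 (SE 0.06, exact permutation p = 0.057). Control replicate 4 and compound 177 replicates 2 and 4, which were low in fibroblast and tendon markers (-0.435, -0.908 and -1.18), had the highest complex I means of their groups (0.046, 0.121 and 0.111), which goes with this explanation. Compound 177 replicate 1 goes against it: it had the highest fibroblast and tendon mean of the 8 arrays (0.832), yet its complex I mean (0.0503) was above that of each control and of compound 177 replicate 3 (0.182 and -0.00834).

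The other values that stood apart from the 3 others of their group were these. Angptl4 was 7.71 in compound 177 replicate 1 (others 6.64 to 6.78), and Cs was 9.51 there (others 9.85 to 9.92). Mrpl18 was 11.77 in control replicate 4 (others 12.48 to 12.62). Nqo1 was 9.39 in control replicate 2 (others 9.02 to 9.05) and 9.89 in compound 177 replicate 2 (others 9.46 to 9.51). Among list means, complex I was 0.046 in control replicate 4 (others -0.12 to -0.09) and fatty acid oxidation 0.13 in compound 177 replicate 4 (others 0.02 to 0.03). Xenobiotic metabolism was 0.42 in control replicate 2 (others -0.07 to -0.02), smooth muscle and pericyte markers 0.30 in control replicate 4 (others -0.09 to -0.06), and thyroid and insulin signalling 0.11 in control replicate 1 (others 0.05 to 0.06).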

How the results depend on the processing

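The fits with or within the normalization set, without both arrays numbered 2, and the exact permutation of list means were chosen after seeing the data. The count of 0 probes past adjusted p held in each alternative run. Probes at an unadjusted p below 0.05, 396 as reported, numbered 126 with median scaling, 954 without a filter (22523 probes tested), 657 with the replicate number as a block, and 253 to 555 with 1 array left out, lowest without control replicate 3. Lists called, 19 as reported, fell to 0 with an estimated correlation, 0 with fry (8 at an unadjusted p below 0.05), 0 by the exact permutation of list means (1 at an unadjusted p below 0.05), 8 within set 2, and 11 to 19 with 1 array left out. Genes past adjusted p over their list alone, counted once per list, 0 as reported, numbered 1 without background correction (Hspe1), 2 without a filter (Hspe1, Fas), 2 with the replicate number as a block (Ifit1, Plvap), 8 within set 1, 16 within set 2 (fewer arrays), and 0 to 15 with 1 array left out: 15 without compound 177 replicate 1 and 8 without control replicate 1, of which 7 and 8 in the slow-fibre list, 4 without control replicate 2 (Hba-a1, Hbb, Hbb-b1, Ahsp), 3 without control replicate 4 (Eln, Agpat2, Plvap) and 2 without compound 177 replicate 3 (Ifit1, Psmb9). Those outside the naming rule were named after their values were seen. Pairing by replicate number changed no other call. In direction, the muscle atrophy list reversed within set 2 (median 0.084) and the slow-fibre list within set 1, where its test pointed up and its median was -0.088. The cause of these changes was not tested. Over all lists and alternatives, calls were lost in the same direction 125 times and gained 12 times. Of 23 alternatives that kept the preset correlation, the extracellular matrix list was called in 23. The authors' normalized table and the series' value table are identical but count separately among the 23, and among the 1440 values that follow. Of 1440 values of named genes, 36 changed sign, in 12 genes that did not pass; Ldha was the one that did so under another scaling. A slide block was not run, since the slides are not given in the sources used here. Signal over background limits the dim genes, and the number of arrays the precision.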

Other observations

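The tests in this part were chosen after the result was seen. Cdkn1a, Tnnt2, Ankrd1 and Fkbp5 were higher in the 2 control arrays of set 1 than in any other array. Cdkn1a, a cell cycle inhibitor, was 7.91 and 8.31 in control replicates 1 and 2 and between 5.11 and 5.71 in the 6 other arrays. Cardiac troponin Tnnt2, which immature muscle also makes, was 9.63 and 11.82 in the same arrays and 7.29 to 8.20 elsewhere. Within set 1, adjusted over the list alone with limma on 2 arrays per group, Cdkn1a (-2.74), Fbxo32 (-1.33), the acetylcholine receptor subunit Chrne (-1.41) and the stretch-responsive Ankrd1 (-1.67) were lower in treated muscle, as was the glucocorticoid target Fkbp5 (-0.83), with adjusted p of 0.000548 to 0.0293 over the list. These genes were chosen after their values were seen. Of these 5 genes, Fbxo32 and Chrne were not highest in the 2 set 1 controls: Fbxo32 was 8.59 and 8.73 there and 8.72 in compound 177 replicate 3, and Chrne was 6.67 and 6.87 there, 8.42 in control replicate 4 and 7.90 in compound 177 replicate 3. In set 2 Cdkn1a differed by 0.29 and Fbxo32 by 0.45. The treated set 1 values of Cdkn1a (5.42 and 5.14) and Chrne (5.41 and 5.14) lie near or below the lowest signals above background, 5.32 to 5.55 depending on the array. Their sizes within set 1 are therefore uncertain. The set 2 values of Cdkn1a were near background too, so the sign of its difference there is uncertain.

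Mrpl18, a mitochondrial ribosomal protein gene, was 8.68 and 8.94 in compound 177 replicates 3 and 4 and between 11.67 and 12.62 in the 6 other arrays. Hspe1, the mitochondrial chaperonin 10, was 9.89 ± 0.02 in control and 10.16 ± 0.04 in treated muscle (SD, n = 4), a difference of 0.26 (SE 0.09) without overlap of the groups, at an adjusted p of 0.9999; it was chosen after its value was seen.

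Other divisions of the 8 arrays into 4 and 4 were run as a check against chance. For probes past adjusted p, 35 of 35 divisions gave as many as the real 0 (highest other 210), and for genes past their list alone, 35 of 35 gave as many as 0 (highest other 47). A real count of 0 is reached by any division whatever the data, so neither says anything about chance. For probes at an unadjusted p below 0.05, 18 of 35 gave as many as 396 (highest other 2151), so over all divisions chance cannot be excluded for that count. For the lists called with the preset correlation, 1 of 35 gave as many as the real 19 (highest other 16), whereas 0 lists were called with an estimated correlation. The other divisions mostly keep some numbered pairs together. If the numbers pair the arrays, which is not settled, the comparable divisions are the 8 that part all 4 numbered pairs. Among these the real one was highest for lists (19, next 16) and for unadjusted probes (396, next 351), but 8 are too few for a share under 0.05. The division along the normalization sets called 210 probes and 0 lists, a structure of the samples, though with the diet in the model the sets differed in 5 probes (2169 against 2151 at an unadjusted p below 0.05); with the set as a block the diets gave 0 probes and 19 lists. Exchanging both arrays numbered 1 called 7 probes: Myh7, Myh3, Atp2a2, Tnnt1, Tnnc1, Tnni1 and Myl2. This division was picked because of the slow-fibre values of these arrays, so the 7 restate that pattern; it called 9 lists, and 1 with an estimated correlation.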
